A study of Rattus norvegicus with 8 samples.

How the data were processed

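Expression was measured in total RNA from right-hemisphere brain tissue of male Wistar rats on 8 Affymetrix RAE 230A arrays, 1 per pool of 2 rats, with 2 independent pools in each of 4 groups, per the labels. The groups were sham or MCAO surgery after 5 days of vehicle or candesartan, taken from the labels of each sample. The treatment protocol of 1 MCAO candesartan array stated no pretreatment, so its group rests on its description. The values were probe set signal intensities on a linear scale, deposited by the authors in 1 table of the series. GCOS, the Affymetrix operating software, was named per the submitters' processing notes, and its version and settings were not given in the sources used here. The 2%-trimmed means of the arrays lay within 0.000426% of each other, so the deposited scaling between arrays was kept. For arrays, their number limits the precision, and with 2 pools against 2 no exact test of a single gene can go below p = 0.333. The p-values given therefore rest on limma's spread pooled over genes and groups. The median difference between the pools of a group was 0.2251 (log2) in MCAO candesartan and 0.1253 to 0.1547 in the other groups. The p-values of contrasts with MCAO candesartan may therefore be too small, and those of MCAO with vehicle and of candesartan after sham too large.

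The table held 15923 probe sets, of which 57 controls were left out. An offset of 370, the 20th percentile of all values, was added before log2, and fold changes are on the log2(signal + 370) scale, which understates the change of dim genes. Probe sets were kept when the signal exceeded 916, the 40th percentile, on at least 2 of the 8 arrays, which left 10310. Gene symbols came from the platform annotation. Counting controls, 12789 probe sets had 1 symbol and 312 several, while 2771 had none when controls were left out. No gene was named from a probe set with several symbols. Of those with 1 symbol, 12754 matched the RefSeq gene table of assembly GRCr8, used for names only, and 0 symbols changed. Of the 10310 tested probe sets 8671 had 1 symbol, and these represented 7466 genes. No coordinates were used.

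All 4 groups were fitted in 1 limma model of group means (version 3.58.1 in R 4.3.3; lmFit and eBayes with a variance trend, 4 residual degrees of freedom), and 7 contrasts were tested with Benjamini-Hochberg adjustment within each. A probe set was called at an adjusted p under 0.05. The 23 gene lists, written before the data were examined, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, using the probe set with the highest mean signal for each gene. They covered immediate early genes, heat shock proteins, the unfolded protein response, cytokines and chemokines, NF-kB targets and mediators, neurotrophic factors, hypoxia, oxidative stress, the renin-angiotensin system, apoptosis, glutamate and GABA transmission, voltage-gated channels, glucocorticoid targets, and markers of 10 cell types or regions.

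The design, the alternatives and the rule for named genes were also fixed before the data were examined. For each MCAO contrast the rule named up to 10 genes each way with the largest changes among called genes whose operated arrays all lay on one side of the sham arrays. For the candesartan contrasts and the interaction it named called genes, and where fewer than 10 were called, the 10 with the smallest p. From each list it allowed up to 4 members with the smallest p, and 18 fixed genes were always included, of which 10 passed the filter. Paip1 fell outside this rule and was named after its values were seen, as were the values without the filter for fixed genes below it.

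The methods were tested on simulated data with independent errors and, for each probe set, the same spread on every array. The counts that follow hold for that setting. For MCAO minus sham in vehicle rats, over 10310 simulated probe sets, 26.9% of the 1.5-fold, 77.6% of the 2-fold and 98.5% of the 4-fold changes were recovered, with 4 false calls beside 135 true ones among 200 changed probe sets. The same changes gave 7 false calls beside 145 true ones for candesartan minus vehicle after MCAO, 4 beside 90 for the interaction, 5 beside 93 for MCAO over both pretreatments and 6 beside 91 for candesartan over both operations. The 2 comparisons with 0 changed probe sets, MCAO with candesartan and candesartan after sham, gave 0 false calls. Alternatives covered the scaling between arrays, the offset, the filter, the variance model, the groups in the fit, a replicate block and leaving out each array. Cyclic loess normalization, array weights and leaving out arrays for the gene lists other than the cytokine and NF-kB lists were added after the data were seen, because MCAO candesartan 2 had a wider signal distribution than the other arrays. The array weights came out equal within each group, 0.472 for both MCAO candesartan arrays. They therefore weighted groups and could not single out that array.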

Results

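Gene expression was measured on Affymetrix RAE 230A arrays in the brains of male Wistar rats given candesartan or vehicle before a transient stroke. Candesartan blocks the angiotensin AT1 receptor, and the vehicle was saline. Rats were injected for 5 days and then underwent either a sham operation or occlusion of the right middle cerebral artery (MCAO) for 90 min followed by reperfusion. RNA was taken 2 h after surgery from a segment of the right hemisphere. Each array held a pool of 2 rats, and 2 independent pools stood for each of 4 groups, sham vehicle, MCAO vehicle, sham candesartan and MCAO candesartan, so that 8 arrays were compared. The labels gave a candesartan dose of 0.1 mg/kg per injection, except for the array MCAO candesartan 2, whose treatment protocol stated no pretreatment and whose group came from its description. The trimmed mean signal of the arrays differed by at most 0.000426%. The median signal split the arrays across the groups: it was 1257.7 to 1292.2 in the 4 sham vehicle and MCAO candesartan arrays and 1319.7 to 1378.2 in the other 4. MCAO candesartan 2 stood apart from the others: the SD of its log2 signals was 1.26 against at most 1.21 elsewhere, and its mean correlation with the other arrays was 0.951 against at least 0.970. The median difference between the 2 pools of a group was 0.23 (log2) in MCAO candesartan and 0.13 in sham vehicle.

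The first comparison asked what MCAO changed at 2 h in rats without the drug. Stress-protein and activity-response transcripts rose steeply. Hspa1a, which encodes an inducible heat shock protein, went from a signal of 1274 ± 97.2 in sham vehicle to 28553.2 ± 1777.8 in MCAO vehicle (mean ± SD, n = 2 pools). Fos, an immediate early transcription factor, went from 960 ± 7.07 to 9441.6 ± 2060.7. The synaptic immediate early gene Arc went from 1464.6 ± 158 to 6087.4 ± 130.0. Cxcl1, a neutrophil-attracting chemokine, went from 76.8 ± 42.8 to 1695.5 ± 58.3, and Ptgs2, the inducible cyclooxygenase, from 497 ± 42.1 to 2055.6 ± 49.5.

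In limma's test 27 of 10310 probe sets, representing 22 named genes, were higher after MCAO in vehicle rats and 0 were lower. On the log2(signal + offset) scale, which understates changes of dim genes, the rise was 4.14 ± 0.29 (SE) for Hspa1a at an adjusted p = 0.000105 and 2.87 ± 0.16 for Fos at an adjusted p = 3.2e-05. A probe set with 2 symbols, therefore left unnamed, rose more than Hspa1a, by 4.51 ± 0.29 (adjusted p = 6.45e-05 by limma). With candesartan it rose by 2.53. The other leading named genes were Atf3 at 2.33, Cxcl1 at 2.21 (adjusted p = 0.0134), the small heat shock protein gene Hspb1 at 2.05, Fosb at 1.94, Arc at 1.82, Ptgs2 at 1.49 (adjusted p = 0.00783), the splicing kinase gene Clk1 at 1.48 and Junb at 1.40. By the naming rule, both MCAO pools lay above both sham vehicle pools for each of these genes. Leaving out any single array of this comparison reduced the count of 27 to between 7 and 9 probe sets, and it was 43 without MCAO candesartan 1. It was 12 without the signal filter, 93 when only the groups compared were fitted and 104 with array weights.

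Immediate early genes rose as a group: 9 of 34 measured members were called, 23 when adjusted over the list alone, all 34 had a change above 0, and the mean was 0.78 ± 0.11 (log2, SE over genes; adjusted p = 9.66e-37 by camera and adjusted p = 0.0459 with an estimated correlation). Heat shock proteins rose by a mean of 0.59 ± 0.24, with 3 of 18 called (Hspa1a, Hspb1 and Dnajb1) and 7 adjusted over the list alone. Their adjusted p was 2.01e-10, and adjusted p = 0.0863 with an estimated correlation. NF-kB targets, adhesion molecules and inflammatory mediators rose by a mean of 0.29 ± 0.10 (adjusted p = 0.000692, and adjusted p = 0.107 with an estimated correlation), although Ptgs2 was the only 1 of 19 members called, also when adjusted over the list alone. Icam1, a leukocyte adhesion molecule, had a change of 0.86 (adjusted p = 0.565) and Timp1 of 0.85 (adjusted p = 0.562). The 10 measured cytokines, chemokines and receptors had a mean of 0.35 (adjusted p = 0.0636), with Cxcl1 called and 2 adjusted over the list alone. This list passed with median-centred arrays (adjusted p = 0.0391), without the signal filter (adjusted p = 0.0444), and without sham vehicle 1 or MCAO vehicle 1 (adjusted p = 0.0499 and 0.0226).

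Markers of astrocytes fell by 0.19 on average, with 16 of 17 members below 0, 0 called and 0 adjusted over the list alone (adjusted p = 1.33e-05, and adjusted p = 0.226 with an estimated correlation). Pyramidal neuron markers fell by 0.16 (adjusted p = 0.00564, and adjusted p = 0.237 with an estimated correlation) and glutamate and GABA transmission genes fell by 0.10 (adjusted p = 0.0143, and adjusted p = 0.163 with an estimated correlation). Without MCAO vehicle 2 both lists gave -0.08 and did not pass (adjusted p = 0.174). The pyramidal list also did not pass without sham vehicle 1 (-0.11, adjusted p = 0.0667), nor the glutamate and GABA list without sham vehicle 2 (-0.08, adjusted p = 0.083) or with a stricter filter (-0.08, adjusted p = 0.114). Among the groups that did not pass the test were hypoxia response genes (0.14, adjusted p = 0.0552), the renin-angiotensin system (-0.13, adjusted p = 0.112), neurotrophic and growth factors (-0.04, adjusted p = 0.696), the unfolded protein response (0.06, adjusted p = 0.387), oxidative stress genes (0.00, adjusted p = 0.607) and voltage-gated channels (-0.01, adjusted p = 0.867). The hypoxia list passed after quantile normalization, with cyclic loess and without the filter (0.15, 0.16 and 0.15, adjusted p = 0.00587, 0.00428 and 0.0302). Voltage-gated channels had a median of 0.03, opposite in sign to their mean, and oxidative stress genes a median of -0.01. Endothelial and mural cell markers had a mean of 0.01 (adjusted p = 0.943). Of these 7 lists 0 members were called except Ppp1r15a, a regulator of the stress-induced block of translation, which rose by 1.01 (adjusted p = 0.0134). Angiotensinogen, Agt, had a change of -0.63 (adjusted p = 0.528), Ace of -0.13 (adjusted p = 0.947), Bdnf of 0.24 (adjusted p = 0.876), its receptor gene Ntrk2 of 0.03 (adjusted p = 0.988) and Nfkbia of -0.10 (adjusted p = 0.962). Oligodendrocyte, neuron and microglia markers did not pass by camera (adjusted p = 0.0665, 0.0636 and 0.106). Without the filter they gave 0.13, -0.0865 and -0.11 and passed (adjusted p = 0.0466, 0.0444 and 0.0302). After quantile normalization the oligodendrocyte list passed too (0.17, adjusted p = 0.00587).

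Il1b, Il6, Tnf, Ccl2, Cxcl2 and the angiotensin receptor genes Agtr1a, Agtr1b and Agtr2 lay below the signal filter. The monocyte chemokine gene Ccl2 gave 66.8 ± 27.9 in sham vehicle and 954 ± 226 in MCAO vehicle, and 66.8 ± 54.1 in sham candesartan and 526 ± 233 in MCAO candesartan (n = 2 pools each). When all probe sets were tested, Ccl2 had a difference between MCAO and sham of 1.59 with vehicle at an adjusted p = 0.0648 and of 1.02 with candesartan at an adjusted p = 0.226. These values did not pass the threshold. Il1b gave 643 ± 46.2 in sham vehicle and 772 ± 153 in MCAO vehicle (adjusted p = 0.991), and Il6 240.2 ± 6.01 and 320.2 ± 108 (adjusted p = 0.993).

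The same operation in candesartan-treated rats raised many of the same activity-response genes. Fos went from 804 ± 68.9 to 7013.4 ± 963 and Arc from 1510.5 ± 55.5 to 6516.3 ± 1009.7. The orphan nuclear receptor gene Nr4a1 went from 2674.4 ± 843 to 10779.4 ± 2440.6. Hspa1a went from 1215.5 ± 97.2 to 9938 ± 5860.8, its 2 MCAO candesartan pools reading 5793.8 and 14082.2. Hspb1 went from 738 ± 6.65 to 1080.5 ± 273.

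In candesartan rats 25 probe sets of 21 genes were called, 22 higher and 3 lower after MCAO. The rise was 2.65 for Fos, 2.58 for Hspa1a (adjusted p = 0.00486), 1.88 for Nr4a1, 1.86 for Arc, 1.58 for Fosb, 1.52 for Cyth3, 1.45 for the G-protein regulator gene Rgs2, 1.45 for the linker histone gene H1f10, 1.43 for Atf3 and 1.28 for Egr4. Ptgs2 rose by 1.11 (adjusted p = 0.0476), while Cxcl1 had a change of 1.37 that did not pass (adjusted p = 0.174). Stard3nl fell by 0.76 (adjusted p = 0.0273). A Paip1 probe set fell by 1.00 (adjusted p = 0.0194) and the other Paip1 probe set had a change of -0.03 (adjusted p = 0.955). The count was 835 without MCAO candesartan 1, which left the divergent array alone in its group, and 5, 8, 14, 14, 15 and 15 without sham candesartan 1, sham candesartan 2, either MCAO vehicle array and either sham vehicle array. It was 16 without the signal filter, 13 with array weights and 11 when only the groups compared were fitted.

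Immediate early genes rose by a mean of 0.68 ± 0.11 in candesartan rats, with 10 of 34 called and 18 adjusted over the list alone (adjusted p = 4.05e-24, and adjusted p = 0.102 with an estimated correlation). Heat shock proteins rose by 0.27 ± 0.14, Hspa1a alone being called and 2 adjusted over the list alone (adjusted p = 0.00233, and adjusted p = 0.320 with an estimated correlation). The NF-kB and mediator list had a mean of -0.06 (adjusted p = 0.657) and the cytokine list of 0.21 (adjusted p = 0.205). Several cell-type markers moved in the same arrays. Pyramidal neuron markers rose by 0.25 and neuron markers by 0.24 (adjusted p = 0.0011 and 0.00241), while markers of astrocytes fell by 0.19, hypothalamus and thalamus by 0.26, choroid plexus and ependyma by 0.31, microglia and macrophages by 0.22 and blood cells by 0.41 (adjusted p between 0.00876 and 0.0456). With an estimated correlation the adjusted p of these 7 marker lists lay between 0.320 and 0.346. Their members called numbered 0, and adjusted over the list alone 2 neuron markers were higher and 6 astrocyte, 3 hypothalamus and thalamus and 1 blood cell markers lower. After quantile normalization and with cyclic loess the neuron list gave 0.13 and 0.14 (adjusted p = 0.2425 and 0.2365) and the microglia and macrophage list -0.19 and -0.18 (adjusted p = 0.0506 and 0.0513), so neither passed. The oligodendrocyte list, not called in the main test (adjusted p = 0.337 by camera), passed with both, at -0.17 after quantile normalization (adjusted p = 0.0115). The 5 lists that fell did not pass without sham candesartan 1 or MCAO candesartan 1. Without sham candesartan 1 the astrocyte, hypothalamus and thalamus, choroid, microglia and blood cell lists gave -0.12, -0.14, -0.18, -0.11 and -0.31. Without MCAO candesartan 1 the same lists gave -0.07, -0.13, -0.21, -0.19 and -0.54. The 2 sham candesartan pools lay apart in these 5 lists. Relative to sham vehicle they gave 0.03 and -0.10 for astrocyte, 0.21 and -0.02 for hypothalamus and thalamus and 0.20 and -0.05 for choroid markers. Microglia markers gave 0.19 and -0.03 and blood cell markers 0.14 and -0.06. For hypothalamus and thalamus, choroid and microglia markers, pools of 1 group thus differed nearly as much as MCAO and sham. With a stricter filter the microglia and choroid lists gave -0.18 and -0.29 and did not pass (adjusted p = 0.12 and 0.077). The blood cell list turned to 0.02 without the signal filter, and without any single 1 of 5 arrays it gave -0.54 to -0.28 and did not pass (adjusted p between 0.0543 and 0.145).

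Over both pretreatments 43 probe sets of 34 genes were higher after MCAO and 0 were lower. Hspa1a rose by 3.36, Fos by 2.76, Atf3 by 1.88, Arc by 1.84, Cxcl1 by 1.79, Fosb by 1.76, Nr4a1 by 1.62, Ptgs2 by 1.30, Rgs2 by 1.30 and Junb by 1.24. Immediate early genes rose by 0.73, with 14 of 34 called and 26 adjusted over the list alone (adjusted p = 6.34e-44, and adjusted p = 0.0325 with an estimated correlation). Hypoxia response genes rose by 0.11 and renin-angiotensin genes fell by 0.17, with 0 members called in either list and 4 and 2 adjusted over the list alone (adjusted p = 0.0123 and 0.0226, and adjusted p = 0.219 for both with an estimated correlation). Heat shock proteins rose by 0.43 (adjusted p = 6.51e-10), astrocyte markers fell by 0.19 (adjusted p = 2.06e-06), microglia and macrophage markers fell by 0.15 (adjusted p = 0.00873), hypothalamus and thalamus markers fell by 0.19 (adjusted p = 0.00873) and blood cell markers fell by 0.26 (adjusted p = 0.0414). With an estimated correlation the adjusted p was 0.0947 for heat shock proteins and between 0.219 and 0.228 for these 4 marker lists. Without MCAO candesartan 1 the hypoxia, renin-angiotensin and 4 marker lists kept their direction but did not pass (adjusted p between 0.0518 and 0.1555). Without sham candesartan 1 the renin-angiotensin, hypothalamus and thalamus, blood cell and microglia lists did not pass, the last giving -0.0922 (adjusted p = 0.164), and without MCAO vehicle 2 the first 3 of these did not, hypothalamus and thalamus markers giving -0.10 (adjusted p = 0.104). The latter did not pass without sham vehicle 2 either (-0.16, adjusted p = 0.0604). The blood cell list did not pass without any single 1 of 6 arrays (-0.33 to -0.17, adjusted p between 0.0613 and 0.199), and without the filter it turned to 0.04 (adjusted p = 0.493). With a stricter filter the hypoxia, renin-angiotensin and blood cell lists gave 0.0993, -0.27 and -0.29 and did not pass (adjusted p = 0.0554, 0.0554 and 0.0705). The count of 43 was 389 without MCAO candesartan 1 and 69 without MCAO candesartan 2, and 21 to 27 without sham vehicle 2, either MCAO vehicle array or sham candesartan 1. The cytokine list had a mean of 0.28 (adjusted p = 0.0667) and passed without sham vehicle 1, MCAO vehicle 1 or sham candesartan 1 (adjusted p = 0.0381, 0.0238 and 0.043). Calls in the vehicle and the candesartan comparison had 16 probe sets in common, against 0.0655 for independent lists. Their changes share no array, but their tests share the spread of each probe set, so the calls are not fully independent. All 27 probe sets called with vehicle had a change above 0 with candesartan. Over the 43 probe sets the median MCAO effect was 1.00 with vehicle and 0.89 with candesartan, a median difference of -0.17, with 25 of the 43 smaller under candesartan. Over pairs of MCAO arrays the difference lay between -0.205 and -0.136, and on these 43 probe sets it lay between -0.211 and -0.0677 with any single array left out, the latter without MCAO vehicle 1. Taken instead over the probe sets called without the array, it was 0.02, 0.54 and 0.03 without sham candesartan 1, MCAO candesartan 1 and MCAO candesartan 2. Over all 10310 probe sets the 2 MCAO effects had a Pearson correlation of 0.147 and a Spearman correlation of 0.0227, computed across probe sets, which are not independent replicates.

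**Figure D1:**
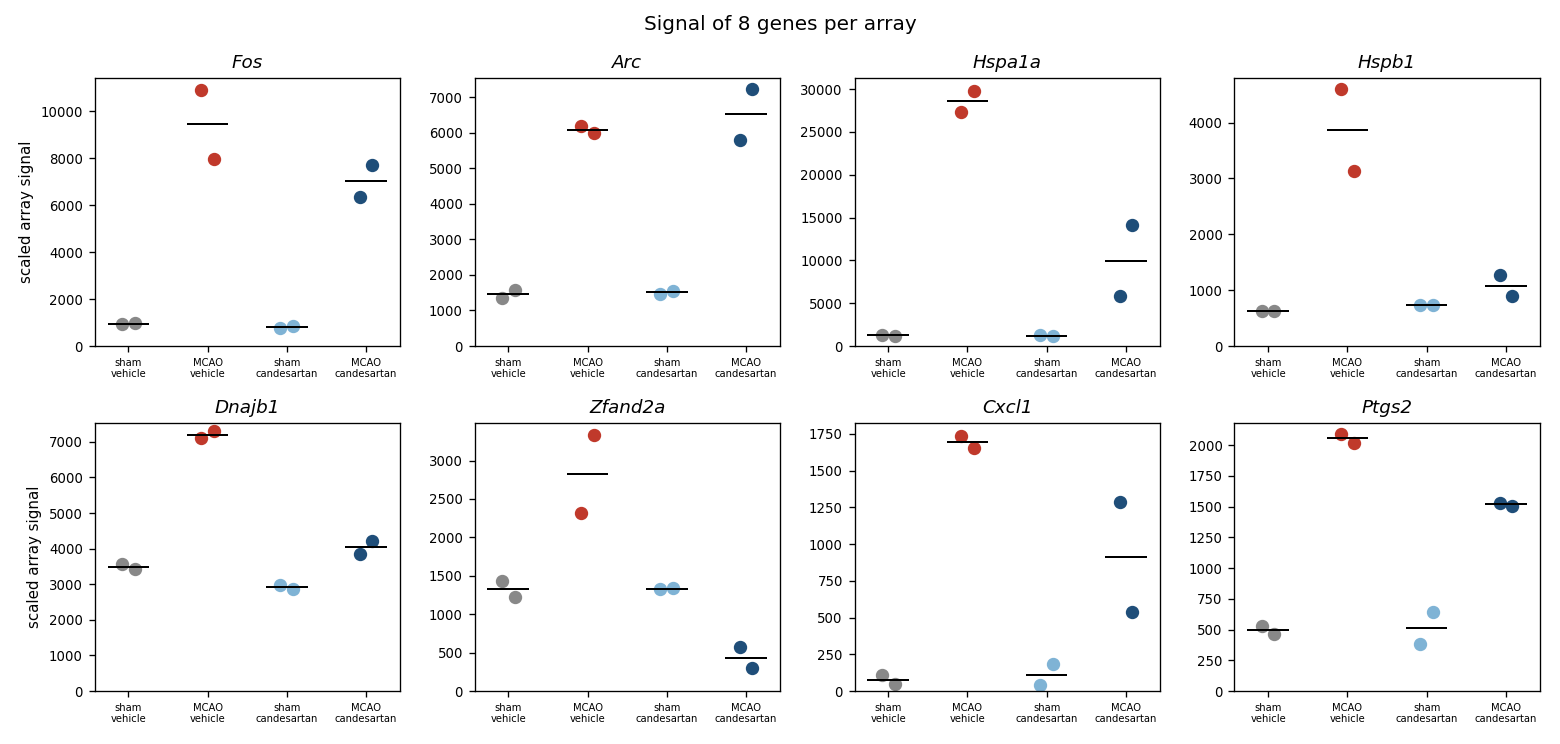
Scaled array signal (vertical axis, linear, from 0) of 8 genes in the 4 groups; each point is the array of 1 pool and each line the mean of 2 pools. Hspb1 reached 3862.2 after MCAO with vehicle and 1080.5 after MCAO with candesartan, while Arc reached 6087.4 and 6516.3.

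The question in the title of the series, whether candesartan alters the response to ischemia, was addressed by comparing MCAO candesartan with MCAO vehicle. Zfand2a, Hspb1 and Dnajb1 were lower with the drug. Zfand2a, a stress-induced gene encoding a zinc finger protein, gave 437 ± 186 with candesartan and 2827.9 ± 713 with vehicle after MCAO, against 1332.2 ± 13.4 and 1326.7 ± 143 after sham surgery. Hspb1 gave 1080.5 ± 273 against 3862.2 ± 1031.5, and Dnajb1, a heat shock co-chaperone, 4033.1 ± 259 against 7195.1 ± 143. Cyth3, H1f10 and the cadherin gene Cdh22 were higher with the drug, Cdh22 at 8897.3 ± 635 against 4678.6 ± 491.

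In limma's test 7 probe sets of 7 genes differed, 3 higher and 4 lower with candesartan. The spread was pooled over groups although the MCAO candesartan pools differed more than the others, so these p-values may be too small. With median-centred arrays 7 were called, 4 higher and 3 lower, of which 6 were among the original 7. Simulated data with 200 changed probe sets gave 7 false calls beside 145 true ones in this comparison. They had the same spread in all groups and independent errors, so they do not give the false-call rate of the 7 calls here. Zfand2a fell by 1.99 ± 0.21 (adjusted p = 0.0155), Hspb1 fell by 1.54 ± 0.20 (adjusted p = 0.0348) and Dnajb1 fell by 0.78 ± 0.11 (adjusted p = 0.04999), its other probe set giving -0.83 (adjusted p = 0.103). Cyth3 rose by 1.44 (adjusted p = 0.0348), H1f10 by 1.504 (adjusted p = 0.0432) and Cdh22 by 0.88 (adjusted p = 0.0432). The seventh was the lower of the Paip1 probe sets at -1.12 (adjusted p = 0.0348), where the other gave 0.04 (adjusted p = 0.936). The next genes by p did not pass: Epas1 had a change of -0.91 (adjusted p = 0.0559), Ccnd2 of 1.02 (adjusted p = 0.0559), Gadd45b of -0.99 (adjusted p = 0.0874) and Cnot1 of -0.91 (adjusted p = 0.0956). The count fell to 0 without any single 1 of the 6 arrays other than the MCAO candesartan pair, without the signal filter, and when only the groups compared were fitted. It was 1 with array weights, 2 with an offset of 1 (0 higher and 2 lower) and 4 with no variance trend or a robust variance. Without MCAO candesartan 2, 7 probe sets were called, 0 higher and 7 lower, of which 2 were among the original 7, and without MCAO candesartan 1 there were 986.

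The heat shock list fell by a mean of 0.30 ± 0.13 under candesartan after MCAO, with 12 of 18 members below 0, Hspb1 and Dnajb1 called and 4 adjusted over the list alone (adjusted p = 0.00547, and adjusted p = 0.312 with an estimated correlation). Hspa1a had a change of -1.61 that did not pass (adjusted p = 0.103). The NF-kB, adhesion and mediator list fell by 0.29 ± 0.09, with 14 of 19 members below 0, 0 called and 2 adjusted over the list alone (adjusted p = 0.00547, and adjusted p = 0.310 with an estimated correlation). Its members nearest the threshold were complement C3 at -0.71 (adjusted p = 0.239), Sod2 at -0.49 (adjusted p = 0.249), Cebpd at -0.58 (adjusted p = 0.264) and Timp1 at -0.95 (adjusted p = 0.275). Without MCAO candesartan 1 the heat shock list gave -0.25 (adjusted p = 0.186) and the NF-kB list -0.26 (adjusted p = 0.158). The cytokine and chemokine list did not pass (-0.18, adjusted p = 0.381, 0 called and 0 adjusted over the list alone), nor did the unfolded protein response (-0.08, adjusted p = 0.3) or oxidative stress genes (-0.05, adjusted p = 0.941), with 0 called and 1 and 2 lower adjusted over the list alone. The cytokine list did not cover Il1b, Il6, Tnf, Ccl2 and Cxcl2, which lay below the signal filter. Immediate early genes had a mean of -0.14, with 21 of 34 below 0, 0 called and 1 lower adjusted over the list alone (adjusted p = 0.2555), but without MCAO candesartan 2 they gave -0.22 and passed (adjusted p = 0.00804). Single inflammatory genes did not pass: Cxcl1 had a change of -0.75 (adjusted p = 0.352), Icam1 of -0.86 (adjusted p = 0.3), Ptgs2 of -0.36 (adjusted p = 0.433), Nfkbia of -0.35 (adjusted p = 0.447) and Fos of -0.40 (adjusted p = 0.343).

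Glucocorticoid targets fell by 0.27 (adjusted p = 0.00547), apoptosis and p53 genes fell by 0.24 (adjusted p = 0.0062) and oligodendrocyte markers fell by 0.18 (adjusted p = 0.0429). With an estimated correlation these gave an adjusted p of 0.312, 0.312 and 0.581. They had 0 members called, and adjusted over the list alone 5 glucocorticoid targets were lower and 1 higher, 0 apoptosis genes differed, and 4 oligodendrocyte markers were lower and 1 higher. Of the 15 glucocorticoid targets 2, Cebpd and Nfkbia, also belong to the NF-kB list, 1, Cdkn1a, to the apoptosis list and 2, Dusp1 and Per1, to immediate early genes. The heat shock and oligodendrocyte lists share 1 member, Cryab. Pyramidal neuron markers rose by 0.29 ± 0.07 with 13 of 15 members above 0 and 5 called adjusted over the list alone (adjusted p = 3.99e-05, and adjusted p = 0.310 with an estimated correlation). Nrgn, with signals of 54170.3 ± 20201.5 against 31417.1 ± 5773.2, had a change of 0.74 (adjusted p = 0.253) and Tbr1 of 0.63 (adjusted p = 0.253). Neuron markers rose by 0.25 (adjusted p = 0.00206) and striatal medium spiny neuron markers by 0.14 (adjusted p = 0.0429), with adjusted p = 0.312 and adjusted p = 0.585 with an estimated correlation. After quantile normalization the neuron list gave 0.11 and the striatal list 0.15, and neither passed (adjusted p = 0.414 and 0.0614). Without MCAO candesartan 1 the glucocorticoid, apoptosis, oligodendrocyte and striatal lists gave -0.32, -0.26, -0.26 and -0.02 and did not pass (adjusted p between 0.0569 and 0.94), and without MCAO vehicle 2 the first 3 gave -0.20, -0.19 and -0.11 and did not pass either (adjusted p between 0.0542 and 0.352). The oligodendrocyte list also did not pass without MCAO candesartan 2 (-0.0958, adjusted p = 0.274), nor the striatal list without MCAO vehicle 1 (0.06, adjusted p = 0.343) or with a stricter filter (0.14, adjusted p = 0.1105), nor both with median-centred arrays (-0.0997 and 0.21, adjusted p = 0.0511 and 0.0609). These neuronal markers moved in the same arrays as the heat shock and NF-kB lists. Agt had a change of -0.14 (adjusted p = 0.812), Ace of -0.11 (adjusted p = 0.829), Bdnf of -0.12 (adjusted p = 0.838) and Ntrk2 of 0.22 (adjusted p = 0.446).

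**Figure D2:**
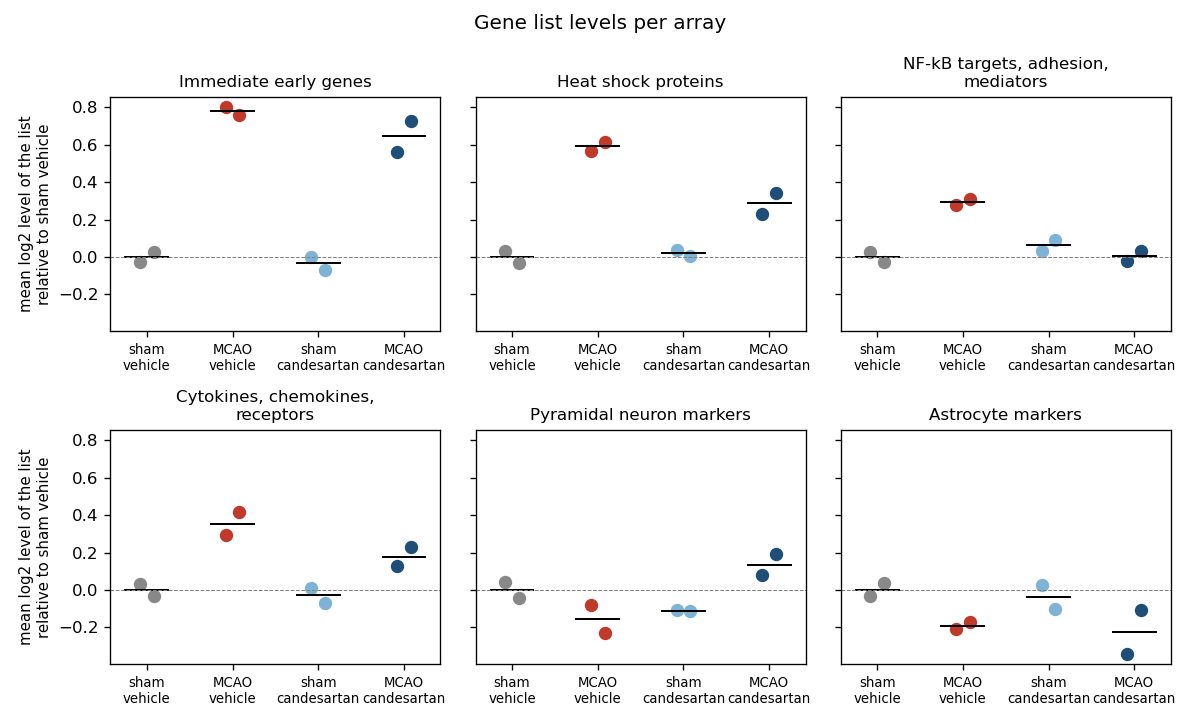
Mean log2 level of 6 gene lists (vertical axis) relative to the mean of sham vehicle in the 4 groups; each point is the array of 1 pool and each line the mean of 2 pools. The heat shock list lay at 0.57 and 0.62 in MCAO vehicle and at 0.23 and 0.34 in MCAO candesartan.

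Without ischemia no difference between candesartan and vehicle was detected. After sham surgery 0 probe sets were called by limma, 404 had an unadjusted p under 0.05 against 515.5 expected by chance, and 0 of 23 gene lists passed, or 2 without sham candesartan 2. The spread used was pooled with the MCAO candesartan pools, which differed more than the sham pools. The p-values after sham may therefore be too large, and the low count does not show an absence of drug effects. The lowest adjusted p of a list was 0.167, for pyramidal neuron markers at -0.11. The genes with the smallest p were Mgll at 0.67, H1f10 at -1.05, Tmem138 at 0.64, Epha5 at -0.96 and Cyth3 at -0.88, all with an adjusted p = 0.693. Over both operations 0 probe sets were called by limma and 731 had an unadjusted p under 0.05. The number called was 303 without MCAO candesartan 1 and 3 without MCAO candesartan 2. Zfand2a was lower by the smallest p, at -0.99 (adjusted p = 0.209), and Cdh22 gave 0.59 (adjusted p = 0.209). Averaged over the operations, heat shock proteins fell by 0.14 (adjusted p = 0.0351), apoptosis and p53 genes fell by 0.11 (adjusted p = 0.0359), and striatal and pyramidal neuron markers rose by 0.11 and 0.09 (adjusted p = 0.0351 and 0.0359). With an estimated correlation the adjusted p of these 4 lists lay between 0.582 and 0.617. They had 0 members called, and adjusted over the list alone 3 heat shock genes were lower and 1 striatal marker higher. All 4 lists failed to pass without sham candesartan 1, where the striatal list gave 0.00684 (adjusted p = 0.59), and without MCAO candesartan 1, where it gave 0.03 (adjusted p = 0.755). Of the 8 arrays, leaving out a single 1 ended the call in 5 cases for heat shock proteins, 5 for apoptosis genes, 4 for striatal and 6 for pyramidal neuron markers, the last giving 0.05 without MCAO vehicle 2 (adjusted p = 0.277). With a stricter filter and with cyclic loess the apoptosis and pyramidal lists kept their direction but did not pass (adjusted p between 0.054 and 0.0999). Immediate early genes gave -0.08 (adjusted p = 0.0748), and -0.13 without MCAO candesartan 2, where they passed (adjusted p = 0.00153), as they did after quantile normalization (adjusted p = 0.0445) and without the filter (adjusted p = 0.0396).

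Whether the MCAO effect itself differed with the drug was tested as an interaction. H1f10 and Cyth3 each had MCAO effects of opposite sign with vehicle and with candesartan: H1f10 gave 954 ± 37.6 in sham vehicle, 246 ± 2.83 in MCAO vehicle, 272 ± 53.3 in sham candesartan and 1379.5 ± 60.5 in MCAO candesartan, and Cyth3 gave 1139.4 ± 30.6, 505 ± 149, 450 ± 10.3 and 1990.3 ± 166. The interaction was 2.55 ± 0.30 for H1f10 and 2.32 ± 0.27 for Cyth3 (adjusted p = 0.0216 for both), both genes being higher in the 4 arrays with the lower median signals, and these were the only 2 of 10310 probe sets called. Simulated data with 200 changed probe sets, with the same spread in all groups, gave 4 false calls beside 90 true ones in the interaction. They do not give the false-call rate of the 2 calls here. Zfand2a had an interaction of -2.00 (adjusted p = 0.0918), Hspb1 of -1.68 (adjusted p = 0.16), Hspa1a of -1.56 (adjusted p = 0.458) and Cxcl1 of -0.84 (adjusted p = 0.585), so a different MCAO effect on these genes under candesartan was not shown gene by gene. Hspb1, Hspa1a and Cxcl1 rose less with the drug. The mean signal of Zfand2a rose after MCAO with vehicle but fell below sham with candesartan. The count was 0 without any single 1 of the 6 arrays other than the MCAO candesartan pair, without the filter, with a stricter filter and with an offset of 1. It was 296 without MCAO candesartan 1 and 7 without MCAO candesartan 2.

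As lists, pyramidal neuron markers differed by 0.40 (adjusted p = 4.81e-06), neuron markers by 0.33 (adjusted p = 0.000193), NF-kB and mediator genes by -0.35 (adjusted p = 0.00803), glucocorticoid targets by -0.32 (adjusted p = 0.0104), heat shock proteins by -0.33 (adjusted p = 0.0167) and apoptosis genes by -0.27 (adjusted p = 0.036) in the interaction. None of these passed with an estimated correlation, at which the lowest adjusted p = 0.271. They had 0 members called, and adjusted over the list alone 4 heat shock genes were lower and 3 pyramidal neuron markers higher. After quantile normalization the neuron list gave 0.17 and did not pass (adjusted p = 0.173). Without MCAO candesartan 1 heat shock proteins gave -0.27 (adjusted p = 0.222) and the NF-kB list -0.32 (adjusted p = 0.078). The heat shock list also did not pass without sham vehicle 2 (-0.295, adjusted p = 0.0692) or MCAO vehicle 2 (-0.30, adjusted p = 0.0649), nor did glucocorticoid targets without MCAO vehicle 2 (-0.25, adjusted p = 0.0649). With a stricter filter the NF-kB and glucocorticoid lists gave -0.34 and -0.26 and did not pass (adjusted p = 0.057 for both). The apoptosis list did not pass without any single 1 of 5 arrays (-0.29 to -0.21, adjusted p between 0.0578 and 0.21), after quantile normalization (-0.20, adjusted p = 0.0572), with cyclic loess (-0.19, adjusted p = 0.0714), without the filter (-0.23, adjusted p = 0.0867) or with a stricter one (-0.21, adjusted p = 0.12). Oligodendrocyte markers gave -0.21 (adjusted p = 0.0562) and passed after quantile normalization at -0.34 (adjusted p = 0.000114). The cytokine list gave -0.15 (adjusted p = 0.745) and immediate early genes -0.10 (adjusted p = 0.745).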

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

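The tests of a smaller responding share of tissue, of the share of neurons, of an unrecorded batch and of the signal distribution behind H1f10 and Cyth3 were chosen only after the result was seen, and so was leaving out arrays for the heat shock and pyramidal lists. The results here were singled out because the MCAO effect differed with the drug in the test of the interaction, which no list passed with an estimated correlation.

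The first pattern is the lower heat shock and NF-kB list means with candesartan, with interactions of -0.33 (-0.3257 before rounding) and -0.35, while the cytokine list did not pass (-0.15, adjusted p = 0.745 in limma's camera). That list did not cover Il1b, Il6, Tnf, Ccl2 and Cxcl2, which lay below the signal filter, so its result says little about induced cytokines. Between the MCAO groups these lists gave -0.30 and -0.29, and -0.36 and -0.32 without MCAO candesartan 2, which argues against that array as the sole source. After quantile normalization they lay at percentiles of 0 and 0.05 of 10000 level-matched lists, which argues against a trend with signal level. An unrecorded batch could set sham vehicle and MCAO candesartan arrays apart from the other 4, as their median signals do (1257.7 to 1292.2 against 1319.7 to 1378.2). With an equal log2 shift in its arrays, it would by itself give equal and opposite changes under the 2 operations. But the lists gave 0.02 and 0.06 after sham surgery, and their means over both operations, -0.1419 ± 0.0353 and -0.113 ± 0.0248 (SE over arrays), lay more than 2 SE from 0. By camera the NF-kB list did not pass over both operations (adjusted p = 0.0748). An artefact of the MCAO candesartan arrays alone was not covered by this test and cannot be told apart from a drug effect after MCAO. If the lists respond in the same tissue, which was not tested, a smaller share of responding tissue should lower the linear rises of all induced genes alike. It need not lower their log2 changes alike. Over all members the mean MCAO effect (log2) with candesartan was 0.868 of that with vehicle for immediate early genes (0.675 to 1.09 over 16 choices of 1 array per group). It was 0.449 for heat shock proteins (0.2999 to 0.629) and -0.199 for the NF-kB list (-0.4545 to -0.00697). On linear signals the ratio was 0.8 for immediate early genes (0.5945 to 1.044) and 0.304 for heat shock proteins (0.167 to 0.453). For the NF-kB list it was -0.0626 (-0.236 to 0.0944), and these ranges lay apart too. Both heat shock ratios lean on Hspa1a, which rose by 4.137 with vehicle and 2.575 with candesartan (log2), a linear ratio of 0.3197. The NF-kB ratio says little about induced genes, as Ptgs2 was its only member called with vehicle. Only if the lists respond in the same tissue do the linear ratios argue against a smaller share as the whole cause, and otherwise it stays open as such. An earlier form took genes called over both pretreatments, a choice that can favour large effects with candesartan, and gave median ratios of 1.09 for 14 immediate early genes and 0.526 for 6 others, of which only Ptgs2 is in the NF-kB list (two-sided exact permutation p = 0.0331, and p = 0.00361 on linear rises, chosen after the first p was known), but genes with shared regulators are not independent and the linear ratios overlapped (0.168 to 1.95, with Gadd45b at 0.168 and Atf3 at 0.437, against 0.106 to 0.645). A reduced response of these lists to ischemia under candesartan stays a hypothesis: a smaller share stays open as part of the cause, since the median MCAO effect of immediate early genes was 0.45 with candesartan and 0.66 with vehicle and they were lower after MCAO without MCAO candesartan 2 (-0.22, adjusted p = 0.00804, against -0.14 with it, adjusted p = 0.2555), a batch added to a drug effect stays possible, and the interactions, at similar sizes, did not pass without MCAO candesartan 1 (-0.27 and -0.32, adjusted p = 0.222 and 0.078), for heat shock also without sham vehicle 2 or MCAO vehicle 2 (-0.295 and -0.30, adjusted p = 0.0692 and 0.0649) and for NF-kB with a stricter filter (-0.34, adjusted p = 0.057).

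The second pattern is the higher pyramidal neuron markers, with an interaction of 0.40 (0.4014 before rounding), beside neuron markers at 0.33 (0.3252). The neuron list gave 0.17 after quantile normalization and did not pass by camera (adjusted p = 0.173), so a level trend stays open for it. Without MCAO candesartan 2 the pyramidal list still rose by 0.23 between the MCAO groups, and it lay at percentile 100 of level-matched lists, which argues against that array or a level trend as the whole source. A higher share of neurons in the dissected segment stays open: 5 lists of non-neuronal markers all had means below 0 between the MCAO groups, although the highest was only -0.0118 ± 0.113, so a rise in one of them was not excluded. The same unrecorded batch, alone or with a drug effect, cannot be told apart from the interaction, since no label separates them, the median signals split the same way, the list was lower in sham candesartan than in sham vehicle, by -0.11, and its mean over both operations, 0.08996 ± 0.0509, lay within 2 SE of 0. An effect of the drug on neurons is untested beyond this.

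The third pattern is the opposite MCAO effect on H1f10 and Cyth3, with interactions of 2.55 and 2.32. A difference in signal distribution between arrays is argued against, as both passed after quantile normalization, the higher adjusted p = 0.0166 by limma. The same unrecorded batch cannot be told apart from the interaction here either: both genes were lower in sham candesartan than in sham vehicle, H1f10 by -1.05 and Cyth3 by -0.88, and of their means over both operations, 0.23 ± 0.15 and 0.28 ± 0.13, that of H1f10 lay within 2 SE of 0 and that of Cyth3 just beyond. A joint effect of the drug and ischemia on these genes is the biological alternative and stays open.

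Apoptosis and p53 genes had an interaction of -0.27 (-0.2674), which did not pass with quantile normalization, cyclic loess, no filter or a stricter filter, nor without any single 1 of 5 arrays (-0.29 to -0.19, adjusted p from 0.0572 to 0.21 in limma's camera). Glucocorticoid targets had one of -0.32 (-0.3195), which gave -0.25 without MCAO vehicle 2 and -0.26 with a stricter filter and did not pass (adjusted p = 0.0649 and 0.057).

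Other splits of the 8 arrays into 4 and 4 were counted in a model of 2 groups. For MCAO against sham, 1 of the 35 splits, the real one, gave as many calls, with 37 probe sets against at most 2 in the others. This argues against chance, but 35 splits are too few to exclude it. For candesartan against vehicle the real split called 0, so that all 35 splits had to give as many, the highest, 37, being that of MCAO against sham, and the count says nothing about chance.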

How the results depend on the processing

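Cyclic loess, array weights and, except for the cytokine and NF-kB lists, arrays left out for gene lists were chosen after seeing the data, and so was leaving out arrays on fixed probe sets. With 2 pools per group, leaving 1 out assumes that the remaining pool varies like the other groups, and without MCAO candesartan 1 that pool is the divergent array. The cause of each change below was not tested unless named. Of 847 values of 45 called gene results under 19 alternatives, 662 stayed past the threshold, 185 fell short and 0 reversed. Of 1215 values of results not called, 35 became called and 11 changed sign. The signal filter limits what is seen of dim genes. The pool numbers did not pair the arrays (correlations of deviations between -0.10 and 0.14), and with a replicate block the calls were 4 for candesartan after MCAO and 0 for the interaction, and the difference in MCAO effect size was -0.20.

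Calls for MCAO with vehicle (27) were 12 without the filter, 104 with array weights and 93 when only the groups compared were fitted, and for MCAO with candesartan (25) they were 16, 13 and 11. For candesartan after MCAO (7) they were 0 without the filter, 1 with array weights, 0 with only the groups compared, 2 with an offset of 1 and 4 with no variance trend or a robust variance. For the interaction (2) they were 0 without the filter, with a stricter filter and with an offset of 1. For candesartan after MCAO (3 higher and 4 lower) median-centred arrays called 4 higher and 3 lower, 6 of them among the original 7, an offset of 1 called 0 and 2, and leaving out MCAO candesartan 2 called 0 and 7. Leaving out 1 array gave 7 to 43, 5 to 835, 21 to 389 (both pretreatments), 0 to 986, 0 to 303 (both operations) and 0 to 296 calls in that order. Candesartan after sham gave 0 calls in every alternative run.

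Lists passing with an estimated correlation numbered 1, 0 and 1 for the MCAO contrasts with vehicle, candesartan and both, and 0 for the drug contrasts and the interaction. Candesartan over both operations had 7 with quantile normalization. Leaving out 1 array gave 4 to 12, 4 to 12, 2 to 10, 2 to 9 (after MCAO), 0 to 2 (after sham), 0 to 8 (both operations) and 3 to 8 (interaction). The NF-kB list after MCAO kept -0.29 with an estimated correlation but fell short (adjusted p = 0.310), and without single arrays it ranged from -0.32 to -0.26, failing at the latter. For candesartan after MCAO the cytokine list ranged from -0.24 to -0.11 without single arrays and passed in no alternative run, while for MCAO with vehicle it passed in 4 alternatives.

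The median difference in the size of the MCAO effect, candesartan against vehicle (-0.17), was -0.13 with quantile normalization, -0.0754 with median-centred arrays, -0.13 with 4 times the offset, -0.23 without the filter, -0.12 with a stricter filter, -0.21 with no variance trend and -0.12 with cyclic loess. Without single arrays it ranged from -0.39 to 0.54, and it reversed without sham candesartan 1 (0.02), MCAO candesartan 1 (0.54) and MCAO candesartan 2 (0.03). These values rest on the probe sets called in each run; on the 43 called with all arrays they ranged from -0.21 to -0.0677 and kept their direction. The correlation of MCAO effects (0.147) was 0.186 with quantile normalization, 0.0932 without the filter and 0.205 with a stricter filter.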
